A study of Caenorhabditis elegans with 2 samples.

How the data were processed

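Peak lists were analysed from ChIP-seq of ATTF-5 tagged with TY1, EGFP and 3xFLAG in whole *C. elegans* young adults of mixed sex, grown for 66 hours. Chromatin was sonicated and recovered with an antibody against GFP. The 2 samples are biological replicates of 1 group, numbered 1 and 3 per the labels. Per the labels, each replicate list was made by the authors from that replicate's alignments and the same control, the pooled list from both replicates and the control, and the thresholded list from the replicate and pooled lists by their reproducibility (irreproducible discovery rate). The peak caller and the read depth were not given in the sources used here, so no value was scaled by depth. Coordinates are in ce11, which has the same sequence as WBcel235.

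The lists are in narrowPeak format with 10 columns. The deposited signal value of each region is a measure of enrichment in the authors' own scale, and it was used as given for ranks and for ratios between replicates. The deposited q-value column is a −log10 q and was used for description only. The score and p-value columns held only fill values and were not used. The thresholded list held 58 regions that share an interval with another region and differ in summit. These were kept as separate peaks, and an alternative dropped summits within 200 bp of a stronger one. In the pooled list 1 summit lay outside its region.

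Genes were taken from Ensembl release 115 and tRNA products from the RefSeq annotation. A protein-coding nuclear gene was called bound when at least 1 summit lay from 1000 bp upstream to 200 bp downstream of its annotated 5′ end. Each summit took 1 annotation class, in the order promoter, 5′ UTR, 3′ UTR, coding exon, noncoding gene or pseudogene, intron and intergenic. Noncoding genes and pseudogenes were counted when a summit lay in the gene or within 200 bp. The piRNA genes were counted among other noncoding RNA genes.

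Shares and counts along the genome were tested by rotating all summits together along the joined nuclear chromosomes, which keeps their spacing, with 10000 rotations and a two-sided permutation p whose smallest value is 0.0002. Replicate overlap was compared with 1000 rotations of the replicate list as description, since the thresholded list was selected on overlap, and its shares carry Wilson intervals at 95%, which cover counting error only. Gene lists (28 families and 9 sets of tissue markers, as worms were taken whole) and 175 gene classes of at least 10 members were tested with Fisher's exact test, two-sided, against all other protein-coding nuclear genes. Odds ratios and 95% intervals were computed after a small constant was added to each count of the table. All p-values were adjusted by the method of Benjamini and Hochberg within each family of tests: 37 lists, 175 classes, 7 annotation classes, the 6 chromosomes together with centres against arms, the noncoding types, and the 6-mers carried forward.

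AT content was measured in the 50 bp on either side of a summit. It was compared with the flanks from 150 to 200 bp of the same peak, and for 1865 promoter peaks with a control position at the same offset from an unbound gene. The test was a two-sided sign-flip permutation test over peaks with 100000 resamples. All 2080 6-mers, with reverse complements joined, were compared within 100 bp of promoter summits and of 5 control positions per peak, 9325 in all. They were found on chromosomes I, III and V and tested on II, IV and X with Fisher's exact test.

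Named genes followed a rule. It took the 25 protein-coding genes nearest to the strongest promoter peaks with a summit within 100 bp in both replicates, the 4 bound members with the strongest peak of each enriched list, up to 2 of each depleted list, attf-5 and unc-119, and the 2 strongest genes of each noncoding type past the threshold. The lists, windows, tests of the main results, threshold of 0.05, naming rule and all alternatives but 2 were chosen before the data were examined. The exceptions are shuffled peak sequences as the 6-mer control and piRNA genes counted apart from other noncoding RNA genes. The tests of explanations and the comparisons of tRNA genes and of peaks away from promoters, given among the observations, were also chosen after the data were examined. Those of promoter base composition, of a chance gap and of a chance difference between the replicate lists were nevertheless fixed before their own results were seen.

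Other settings tried were the peaks with signal above the median, the strongest regions of each replicate without the other, the strongest regions of the pooled list, summits within 200 bp of a stronger one dropped, and regions within 50 kb of attf-5 and unc-119 left out. For genes they were a window from 500 bp upstream to 100 bp downstream, the nearest 5′ end within 2000 bp, a rotation test, a background of genes with any pooled region, and separate adjustment of tissue and family lists. For overlap they were any shared base, 50% reciprocal overlap and summits within 50 bp. For sequence they were AT windows of 25 and 100 bp, control positions in place of flanks, exchanged chromosome sets and a 6-mer window of 50 bp.

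The methods were tested on simulated data. A planted gene list was recovered in 20 of 20 sets. Without a planted list, 10 of 740 list tests were called, 4 of them for histones and 2 for the spliceosome. The cause of these calls was not tested. Fisher's exact test takes genes as independent, although a peak can serve several genes. Its p-values can therefore be too small for lists whose members share peaks. The rotation test called 0 of 20 rotated sets and 20 of 20 sets with 200 summits moved to promoters. No 6-mer was called between control sets, and 9 of 10 planted in 10% of windows were recovered. The sign-flip permutation p was 0.0661 between control sets and 1e-04, the smallest its resamples give, with 2 points of AT content taken off. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.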

Results

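The binding of ATTF-5, a *Caenorhabditis elegans* protein named as an AT-hook transcription factor, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole young adults 66 hours old. The animals carried an integrated transgene of attf-5 fused to a TY1, EGFP and 3xFLAG tag together with an unc-119 rescue gene, and chromatin was recovered with an antibody against GFP. There was 1 group of 2 biological replicates, numbered 1 and 3 in the labels. The values are the authors' peak lists in ce11 coordinates, each with a signal value and a −log10 q per region. A list of 30000 regions came from replicate 1, 28299 from replicate 3 and 30000 from the pooled alignments. By its label the pooled list holds peaks and background. The lowest −log10 q was 0.0602 in the pooled list, 0.0608 in replicate 1 and 0.0177 in replicate 3, so regions of these lists can be background. Of the regions, 3331 passed the authors' reproducibility threshold. These 3331 are called peaks here. Their median width was 424 bp and their signal ran from 89.6 to 2844, with a median of 142.7. Read depth was not given in the sources used here, and with a single group no test between conditions was possible. Tests below take peaks or genes as units, which are not biological replicates.

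The peaks had been kept by the authors for their reproducibility between these same replicate lists, so a high share with a summit in both was built in. Without that selection, 2319 (69.6%) of the 3331 strongest regions of replicate 1 had one of the 3331 strongest regions of replicate 3. Of the 3331 peaks, 3258 (97.8%, 95% Wilson interval 97.3 to 98.3%) had a replicate 1 summit within 100 bp and 3252 (97.6%, 97.1 to 98.1%) had a replicate 3 summit there. A summit in both replicates was found for 3182 peaks (95.5%, 94.8 to 96.2%). When the replicate lists were rotated along the genome, a mean of 1.87% (SD 0.242) had one; given the selection, this is a description and not a test. The median distance between summits was 8 bp for replicate 1 and 13 bp for replicate 3. Signal values had a Spearman rho of 0.716 between the replicates across these 3182 peaks, which are not independent replicates and were selected for reproducible rank, so the rho is a description too. The log2 ratio of replicate 1 to replicate 3 had a median of 0.13 and an SD of 0.52, and 207 peaks (6.51%) lay more than 2-fold from the median ratio. The share of peaks found in both replicates fell to 76.5% when summits had to lie within 50 bp.

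Peaks were concentrated at promoters of protein-coding genes and scarce in coding exons. A promoter window, taken from 1000 bp upstream to 200 bp downstream of an annotated 5′ end, held 1891 of the 3331 summits (56.8%), which was 2.64 times the 21.5% (SD 0.773) of rotated summits. Only 58 summits (1.74%) lay in coding exons, where rotation placed 19.6%. Introns held 13.7% of summits against 29.9% of rotated ones, and intergenic sequence held 17.1% against 21.6%. Noncoding genes and pseudogenes held 7.90% against 4.09%. Each of these 5 shares differed from rotation (two-sided permutation p = 0.0002, the smallest that 10000 rotations can give; adjusted p = 0.00028 over 7 classes), and 3′ UTRs were also low at 1.68% against 2.58% (adjusted permutation p = 0.00187). The low share in 3′ UTRs was absent without replicate 3, where the strongest regions of replicate 1 gave 2.82% against 2.58% (adjusted permutation p = 0.424). The 38 summits in 5′ UTRs did not differ from rotation (adjusted permutation p = 0.0706). Each summit took 1 class, so the excess at promoters by itself lowers the other shares. The low intergenic share therefore does not show that such sequence was avoided, and shares among summits outside promoters were not tested. The median offset of promoter summits from the nearest annotated 5′ end was −190 bp, with quartiles of −339 and −92 bp, where negative values lie upstream.

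**Figure D1:**
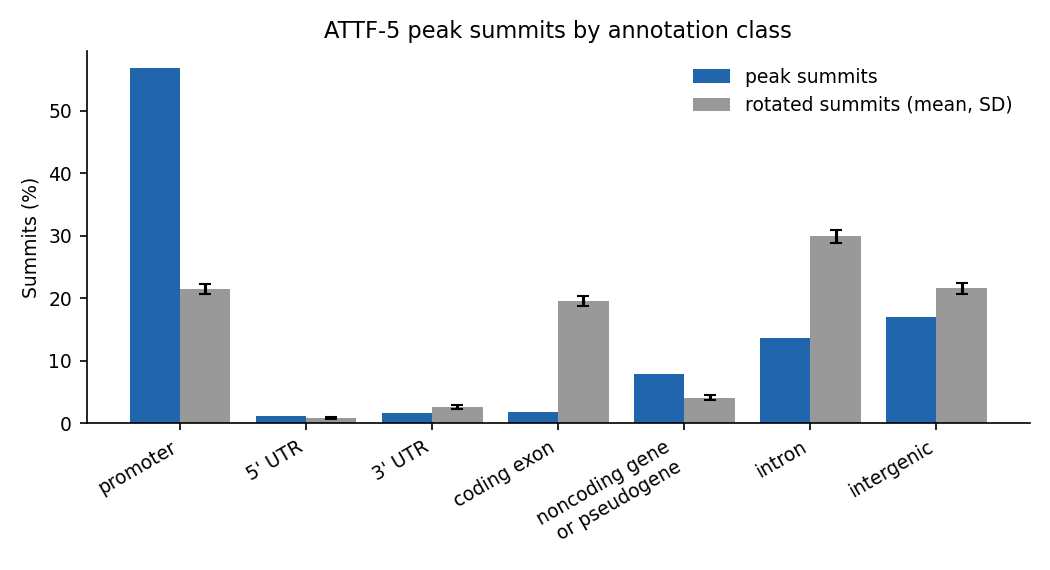
Share of the 3331 ATTF-5 peak summits (blue) and of rotated summits (grey, mean and SD over 10000 rotations) in each annotation class, in percent. Promoters hold 56.8% of summits and 21.5% of rotated ones, while coding exons hold 1.74% and 19.6%.

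Chromosomes I and III carried the densest binding and chromosome V the sparsest. There were 46.5 peaks per Mb on III, 43.1 on I, 34.9 on II, 30.3 on IV, 27.6 on X and 23.3 on V. The centres of the autosomes held 42.8 peaks per Mb and their arms 30.2, a ratio of 1.42 against 1.01 (SD 0.177) under rotation. None of these 7 comparisons passed the threshold when adjusted together. The nearest were chromosome III (permutation p = 0.0076, adjusted p = 0.0532) and centres against arms (permutation p = 0.0174, adjusted p = 0.0609), while III alone passed when the 6 chromosomes were adjusted without the arms (adjusted permutation p = 0.0456).

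The strongest peaks were near genes of varied function, ribosomal protein genes among them, and most of the 25 genes named by the rule belong to none of the fixed lists. The highest signal of all, 2844, was at chromosome III 10758988 to 10759581, with its summit at −58 bp from the 5′ end of tasp-1 (WBGene00010480) and also in the window of K01G5.10. Replicate 1 gave 1488 and replicate 3 gave 1361 there, the highest value in each list. The next were a peak at III 13643502 to 13644003 (signal 1916) with its summit at −166 bp from the 5′ end of drr-2, also in the window of the histone methyltransferase gene set-16, and a peak at III 3867306 to 3867804 (1716) whose summit lay at −273 bp from the 5′ end of the ribosomal protein gene rpl-3. The peak of cdc-48.1 (II 10563340 to 10563794, signal 1565), which encodes the AAA ATPase p97, came next by signal. Among the 25 genes named by the rule were the ribosomal protein genes rpl-3, rpl-35, rpl-15, rpl-12 and rps-28, whose signals ran from 866 to 1716. The peaks assigned to Y17G9B.5, hsr-9 and ekl-4 also lay in the windows of rpl-20, rps-19 and rps-20. Others were iff-2, which encodes the translation factor eIF5A (signal 1092), sec-61.G, which encodes a subunit of the ER protein channel (1167), the cytochrome c oxidase gene cox-5B (870), the Integrator subunit gene ints-4 (978, with its summit at 36 bp downstream of the 5′ end), the mRNA capping enzyme gene cel-1 (884), the ataxin-2 gene atx-2 (852) and the histone acetyltransferase gene hat-1 (833). The remaining ones were K12H4.5, Y71H2AM.20, wip-1, ecps-1, rib-2, Y77E11A.7 and ntl-11, with signals from 805 to 1512. All 25 had a summit within 100 bp in both replicates, as the rule required. The rule covers promoter windows, and the peak ranked 8 by signal (1328, at I 2639584 to 2640074) lay outside them, 1167 bp downstream of the 5′ end of F40E3.3.

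A promoter peak was found at 2461 of 19973 protein-coding genes (12.3%). Many peaks served more than 1 gene: 642 summits lay in the windows of several genes, and 595 of these lay between genes transcribed away from each other. More than 1 summit was present at 115 genes. Of 77 protein-coding genes named by the rule, 59 stayed bound when each peak was given to the nearest 5′ end alone. Those that did not were rpl-20, rps-19, mrpl-37, mrpl-45, eef-1A.1, prp-19, rsp-2, pbs-2, cct-7, cct-8, cct-1, vha-8, set-16, lin-54, glr-6, col-38, col-2 and bath-42. Of the 77, 68 stayed bound with a window from 500 bp upstream to 100 bp downstream.

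Genes of basic cell functions were bound far more often than other genes. Of 81 ribosomal protein genes, 66 (81.5%) had a promoter peak, an odds ratio of 31.3 (95% interval 18 to 54.6, with 0.5 added to each count). Their strongest peaks were those of rpl-3 (signal 1716), rpl-20 (1443), rpl-35 (1362) and rps-19 (1323). Of 37 lists fixed before the data were examined, 11 were enriched among bound genes and together held 645 genes, of which 306 (47.4%) were bound. These 306 made up 12.4% of the 2461 bound genes, so most bound genes were in none of the 11 lists. The enrichment of ribosomal protein genes had an adjusted p of 1.01e-44 in Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 37 lists, the test used for every list. This test takes genes as independent, so its p-values can be too small for lists whose members share peaks.

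Protein synthesis and RNA processing genes made up much of the enriched set. Translation factors and aminoacyl-tRNA synthetases were bound at 31 of 63 genes (odds ratio 6.97, interval 4.26 to 11.4, adjusted p = 8.69e-12, Fisher's exact test), with ears-2 (signal 581), eef-1A.2 (555), eef-1G (540) and eef-1A.1 (515) at the top. Spliceosome genes were bound at 22 of 41 (odds ratio 8.27, interval 4.51 to 15.2, adjusted p = 9.74e-10, Fisher's exact test), led by prp-19 (726), by rsp-1 and rsp-2, which share a peak of 574, and by prp-8 (565). Mitochondrial ribosomal protein genes had the smallest odds ratio of the 11 lists, 3.54 (interval 2.16 to 5.82, adjusted p = 1.56e-05, Fisher's exact test), with 23 of 70 bound. Their strongest peaks, at mrpl-49, mrpl-15, mrpl-37 and mrpl-45, had signals from 281 to 434, and that of mrpl-49 is also the peak of the ribosomal protein gene rpl-28.

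Genes of energy metabolism and protein quality control were also bound at high rates. The mitochondrial respiratory chain list was bound at 20 of 41 genes (odds ratio 6.83, interval 3.73 to 12.5), with cox-5B (870), cox-5A (766), atp-1 (470) and atp-3 (469) the strongest. Similar shares were bound in the vacuolar ATPase, with 10 of 20 genes (odds ratio 7.14, interval 3.03 to 16.8) led by vha-8 (467), vha-1, vha-13 and vha-12, the proteasome, with 16 of 33 (odds ratio 6.75, interval 3.44 to 13.2) led by rpn-9 (463), rpn-11, rpn-3 and pbs-2, and autophagy, with 12 of 25 (odds ratio 6.61, interval 3.06 to 14.3) led by atg-9 (308), epg-4, lgg-2 and lgg-1. Chaperone genes were bound at 26 of 66 (odds ratio 4.69, interval 2.87 to 7.67), led by the chaperonin genes cct-7 (560), cct-8 (489) and cct-1 (458) and the BiP gene hsp-3 (441). Adjusted p-values of these 5 lists lay between 5.03e-08 and 1.05e-04 in Fisher's exact test.

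Nuclear regulators formed the last part of the enriched set. Chromatin regulator genes were bound at 46 of 123 (odds ratio 4.33, interval 3.00 to 6.25, adjusted p = 8.69e-12, Fisher's exact test), led by set-16 (1916), lin-54 (1016), hat-1 (833) and the CBP acetyltransferase gene cbp-1 (740). The set-16 and lin-54 peaks are those of drr-2 and rpl-12, whose 5′ ends are nearer, and cbp-1 was not bound in the smaller window. Cell cycle and DNA replication genes were bound at 34 of 82 (odds ratio 5.12, interval 3.30 to 7.94, adjusted p = 1.91e-10, Fisher's exact test), led by cdc-48.1 (1565), cdk-7 (597), the PCNA gene pcn-1 (538) and the kinetochore gene knl-3 (460). When only the 7709 genes with any pooled region in their window were compared, 8 of the 11 lists stayed past the threshold and 3 did not, namely mitochondrial ribosomal proteins (adjusted p = 0.171), the proteasome (0.0644) and the vacuolar ATPase (0.0640, all by Fisher's exact test). Odds ratios were lower there for all 11, among them 12.6 for ribosomal proteins, 3.31 for translation factors, 3.33 for the spliceosome, 3.00 for chromatin regulators and 2.15 for the cell cycle.

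Chemoreceptor genes and 7 other lists were bound less often than other genes. Of 1310 chemoreceptor genes, 10 (0.763%) had a promoter peak (odds ratio 0.0534, interval 0.0291 to 0.0982, adjusted p = 4.95e-60, Fisher's exact test), the strongest at sri-5 (444) and sre-23 (326). Neurotransmitter receptor and ion channel genes were bound at 5 of 289 (odds ratio 0.136), with kvs-3 and glr-6 the strongest, and neuropeptide and insulin genes at 2 of 144 (odds ratio 0.124), nlp-40 and nlp-76. The odds ratio of the neuropeptide and insulin list was 0.174 to 0.239 without a replicate. Of its named genes, nlp-40 was not bound without replicate 3, and neither was bound with peaks of signal above the median. The list of lectin, lysozyme and antimicrobial genes, defined by symbol, was bound at 9 of 363 (odds ratio 0.188), led by fipr-17 and ech-5; ech-5 and ech-1.2 among the 9 are enoyl-CoA hydratase genes that the symbol rule took in. F-box and MATH domain genes were bound at 20 of 445 (odds ratio 0.337), led by bath-42 and fbxa-90, cuticle collagen genes at 7 of 176 (odds ratio 0.313), led by col-38 and col-2, and hedgehog-related genes at 1 of 85 (odds ratio 0.126), grl-26. The peaks of bath-42, fbxa-90, col-38 and col-2 are also those of prp-8, efl-1, rpl-5 and ndc-80, whose 5′ ends are nearer. No major sperm protein gene was bound among 48, a call that was lost with peaks of signal above the median (adjusted p = 0.0815), with the nearest 5′ end (0.0685) and with genes that had any pooled region as background (0.244, all by Fisher's exact test). The adjusted p-values of these other 7 lists ran from 1.18e-10 to 0.00635 in Fisher's exact test. Under rotation of the summits, which asks instead whether binding exceeded that of random positions, chemoreceptors alone of the 8 depleted lists fell below chance (adjusted permutation p = 4.62e-04), with 10 genes bound against a mean of 49.9 (SD 9.82).

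**Figure D2:**
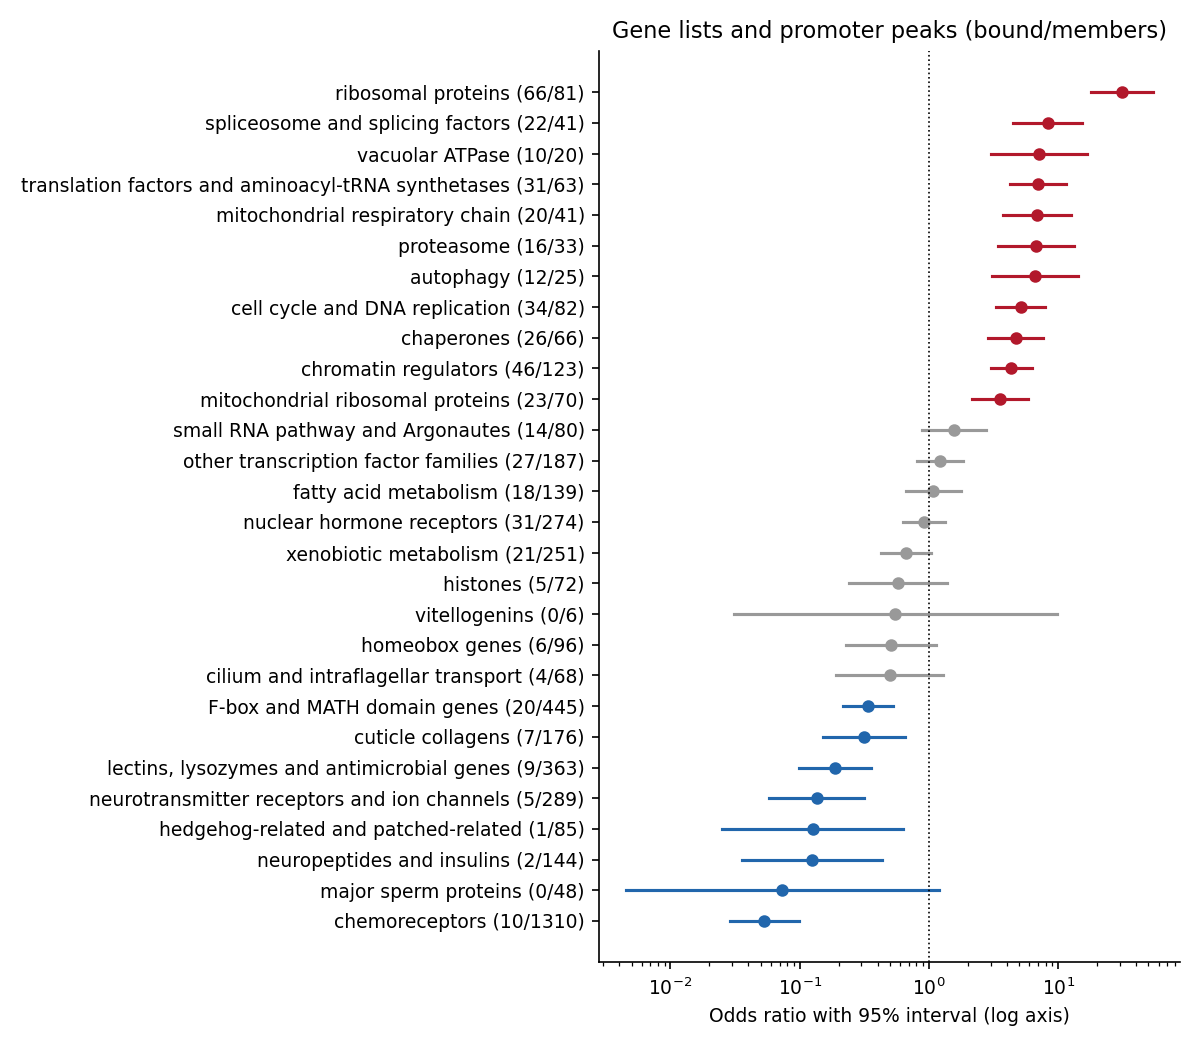
Odds ratio of having a promoter peak for the 28 gene family lists, with 95% intervals on a log axis and the bound and total members in parentheses; 0.5 was added to each count. Red marks the 11 lists enriched at an adjusted p under 0.05, blue the 8 depleted lists and grey the rest; the interval of major sperm proteins spans 1.

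No list of tissue markers, of 19 to 61 genes each, passed this threshold. Power was not computed. Family lists as small passed when strongly enriched, such as the vacuolar ATPase (10 of 20 bound) and autophagy (12 of 25). Weaker enrichment and depletion of tissue lists could have been missed. Only neuron markers, at 13.3%, were bound above the 12.3% of all genes. The 9 lists covered neurons (4 of 30 bound), body-wall muscle (1 of 30), pharynx (1 of 25), intestine (2 of 36), epidermis (0 of 33), germline and oocytes (7 of 61), sperm (0 of 29), somatic gonad, vulva and uterus (1 of 27), and coelomocytes with the excretory cell (2 of 19). The lowest adjusted p among them was 0.0531, for epidermis, in Fisher's exact test. Histone genes (5 of 72), nuclear hormone receptors (31 of 274), homeobox genes (6 of 96), other transcription factor families (27 of 187), cilium genes (4 of 68), small RNA pathway genes (14 of 80), xenobiotic metabolism (21 of 251), fatty acid metabolism (18 of 139) and vitellogenins (0 of 6) did not pass either. Some of these calls depended on the setting. Xenobiotic metabolism passed on the depleted side with the strongest regions of replicate 1 alone (adjusted p = 0.0244), with peaks of signal above the median (0.00507) and with genes that had any pooled region as background (0.00645, all by Fisher's exact test). Epidermis did so with replicate 1 alone (0.0490) and with that background (0.0458), homeobox genes with the smaller window (0.0441) and cilium genes with the nearest 5′ end (0.00747), while other transcription factor families passed on the enriched side there (0.00747, all by Fisher's exact test). Against rotated summits, 6 of these lists were bound more often than random positions, with adjusted permutation p-values up to 0.0390. The folds over the rotated mean were 4.59 for small RNA pathway genes, 3.79 for other transcription factor families and 3.39 for fatty acid metabolism. They were 3.02 for germline and oocyte markers, 2.97 for nuclear hormone receptors and 2.19 for xenobiotic metabolism. Protein-coding genes as a whole were also bound more often than random positions, so these folds show no enrichment over other genes. Germline and oocyte markers (11.5% bound), nuclear hormone receptors (11.3%) and xenobiotic metabolism (8.37%) lay below the 12.3% of all genes.

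The same division appeared among gene classes defined by symbol alone. Of 175 classes with at least 10 protein-coding members, 21 were enriched among bound genes and 21 were depleted. The small ribosomal subunit class rps had 27 of 31 members bound (odds ratio 43.9, adjusted p = 4.13e-19, Fisher's exact test) and the large subunit class rpl had 38 of 47 (odds ratio 29.3, adjusted p = 1.66e-24, Fisher's exact test). Classes wholly or mostly outside the fixed lists included the nuclear pore genes npp (15 of 26, adjusted p = 1.30e-06), the vacuolar sorting genes vps (14 of 31, adjusted p = 9.72e-05), the Integrator genes ints (7 of 11, adjusted p = 0.00112), the secretory pathway genes sec (9 of 19, adjusted p = 0.00198), the RNA polymerase II subunit genes rpb (6 of 11, adjusted p = 0.00647) and the TFIID genes taf (7 of 17, adjusted p = 0.0146), all by Fisher's exact test over the 175 classes. Among depleted classes, the chemoreceptor class str had 0 of 193 members bound (adjusted p = 7.26e-10) and the lectin class clec had 4 of 240 (adjusted p = 7.41e-08, Fisher's exact test). With the 7709 genes that had any pooled region as background, 8 classes passed the threshold on the enriched side.

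Genes for transfer RNAs and small nucleolar RNAs carried peaks far more often than rotated summits did. A summit lay in or within 200 bp of 294 of 612 tRNA genes (48.0%), 31.2 times the 9.41 genes (SD 3.33) reached under rotation. The strongest were a tRNA-Asn gene, F41D9.t3 (X 8404499 to 8404571, signal 329), and a tRNA-Glu gene, C28G1.t1 (X 8836113 to 8836184, signal 325). The fold was 13.8 for snoRNA genes (83 of 346, rotated mean 6.02), with ZK994.7 (signal 583) and C51F7.3 (478) the strongest, and 8.14 for snRNA genes (18 of 129, rotated mean 2.21), with sls-2.1 (423) and R07E5.16 (373). Other noncoding RNA genes, piRNA genes included, were bound at 738 of 23421, 2.02 times rotation, with F26F4.14 (765) and linc-128 (753) the strongest. MicroRNA genes were bound at 12 of 261, 2.85 times rotation (adjusted permutation p = 0.0103), with cel-mir-5549 (515), whose peak is also that of eef-1A.1, and cel-mir-5595 (388.5). Many of these genes lie in promoter windows, which are themselves enriched: those outside numbered 237 of the 294 tRNA genes with a peak, 56 of 83 for snoRNA, 9 of 18 for snRNA, 7 of 12 for microRNA and 405 of 738 for other noncoding RNA. Pseudogenes had few, 29 of 2128 against 120.8 (SD 13.4), with WBGene00013638 (767) and WBGene00023323 (637) the strongest. The 5 types other than microRNA and rRNA had an adjusted permutation p of 2.8e-04, and no rRNA gene of the 20 had a peak (rotated mean 0.522, permutation p = 1). When piRNA genes were counted apart, a choice made after the data were seen, they had a peak at 32 of 15363 against 210.9 (SD 59.2), the strongest at 21ur-13751 (627) and 21ur-12279 (470), and the remaining noncoding RNA genes at 706 of 8058, 4.58 times rotation (adjusted permutation p = 2.67e-04 for each).

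**Figure D3:**
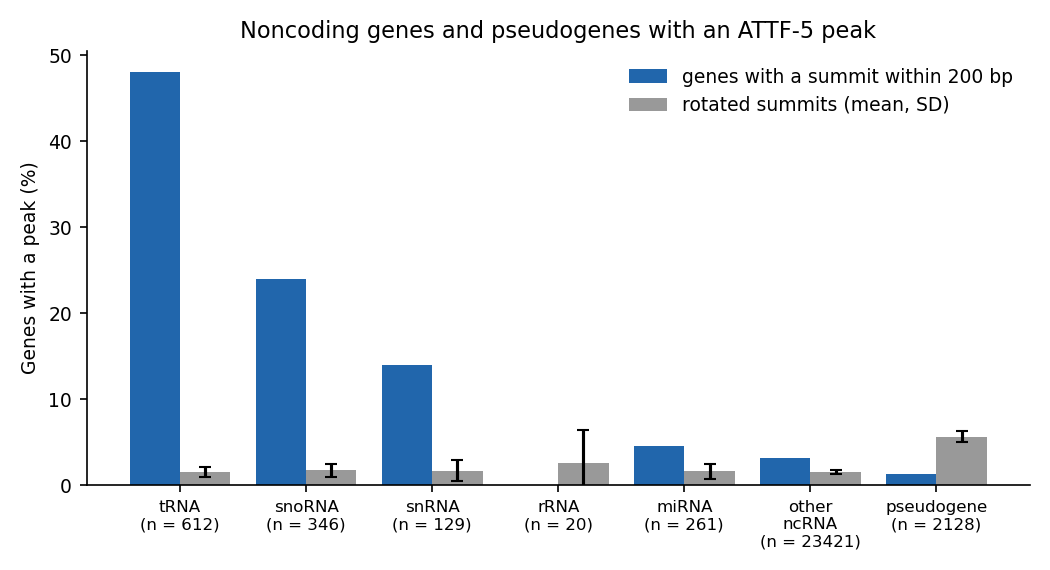
Share of annotated noncoding genes and pseudogenes with an ATTF-5 summit in the gene or within 200 bp of it (blue), and the share reached by rotated summits (grey, mean and SD over 10000 rotations), in percent. The tRNA share is 48.0% of 612 genes and the snoRNA share 24.0% of 346.

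DNA at the summits was poorer in A and T than its surroundings, although the protein is named for AT-hooks, motifs that contact AT-rich DNA. The 50 bp on either side of a summit held 53.5% A and T (SD 8.21 over 3331 peaks), against 63.7% in flanks of the same peaks 150 to 200 bp away, and 64.6% in the genome. The paired difference was −10.2 percentage points (SE 0.194), and 82.2% of peaks were lower at the summit than in their flanks (sign-flip permutation p = 1e-05, the smallest that 100000 resamples can give). For 1865 promoter peaks the summit held 53.8%, against 66.0% at the same offset upstream of unbound genes, a difference of −12.2 points (SE 0.269, permutation p = 1e-05). Stronger peaks were lower still, with 50.1% (SD 7.18) in the 833 peaks with the highest signal and 55.7% (SD 8.23) in the 833 with the lowest.

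Several 6-mers were more frequent at promoter summits than at control positions, which were richer in A and T, and which 6-mers led depended on the control. The 6-mer GAGCGC or its reverse complement lay within 100 bp of 23% of promoter summits on chromosomes II, IV and X and of 2.46% of control positions there (odds ratio 11.8, adjusted p = 2.27e-82, Fisher's exact test). ACGCAG was found at 24.4% against 3.96% (odds ratio 7.84, adjusted p = 3.16e-69), and the overlapping GACGCA at 23.7% against 4.74% (adjusted p = 1.87e-57, Fisher's exact test). The repeat GAGAGA was found at 35.1% against 12.7% (odds ratio 3.74, adjusted p = 5.34e-48, Fisher's exact test). Of 646 6-mers found on chromosomes I, III and V, 557 passed on the other chromosomes. With shuffled copies of the same peak windows that keep each window's dinucleotides as control, an alternative chosen after seeing the data, 266 passed. The lowest p was that of GAGAAA (48.7% against 21.4%), and AGAAAA (54% against 31.6%) and AAAATA (43.1% against 24.0%) passed too, although AGAAAA did not pass against control promoters (52.8%, odds ratio 1.05, adjusted p = 0.537, Fisher's exact test) and AAAATA was not among the 646. Others that passed were ACGCAG (24.4% against 6.88%), GAGAGA (35.1% against 13.9%) and GAGCGC (23% against 8.50%).

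**Figure D4:**
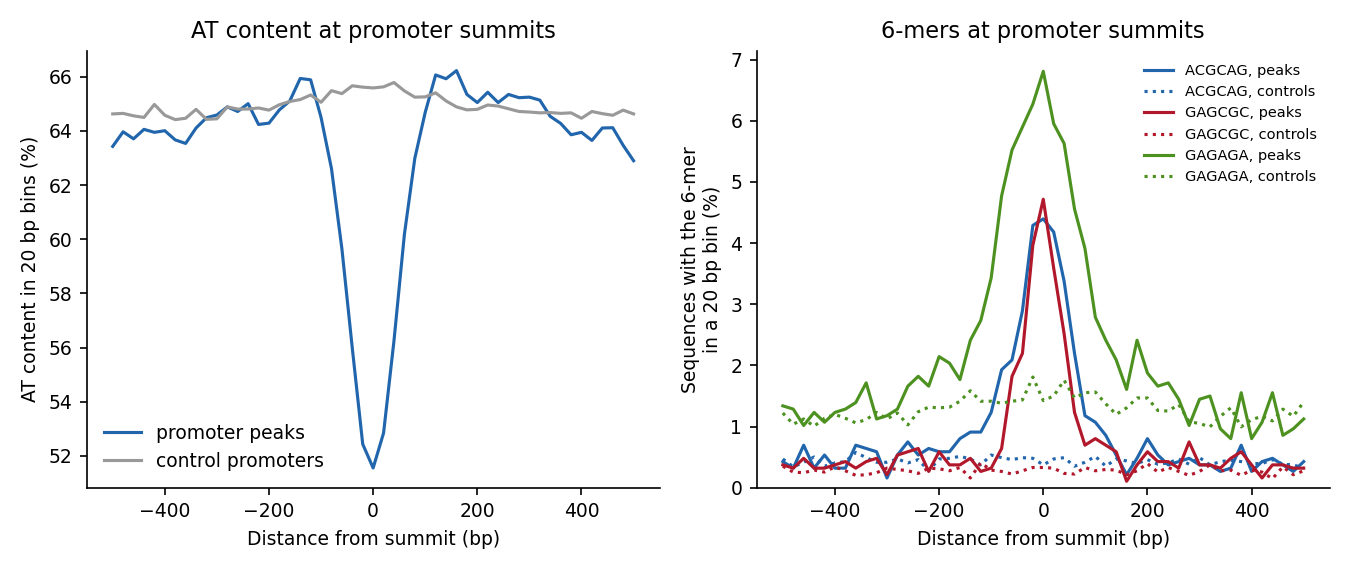
Left, mean AT content in 20 bp bins around 1865 promoter summits (blue) and control positions of unbound promoters (grey), in percent. Right, share of sequences with each 6-mer in a 20 bp bin, in percent, for the same summits (solid) and controls (dotted); ACGCAG reaches 4.40% at the summit against 0.375% in controls.

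The genes carried by the transgene, attf-5 and unc-119, had no peak between 1000 bp upstream and the end of the gene. At attf-5 (WBGene00020214, X 788353 to 796154, plus strand) the replicate 3 list had 4 regions, the strongest with a signal of 88.1 and a rank of 1141 of 28299, at summit 788236 just upstream of the annotated gene start. The replicate 1 and pooled lists had none, and in replicate 1 no summit lay between 770923 and 806680, a stretch of 35757 bp. At unc-119 (WBGene00006843, III 10902641 to 10908935) the strongest region ranked 8889 of 30000 in replicate 1, 5146 of 28299 in replicate 3 and 5002 of 30000 in the pooled list. Regions of the replicate and pooled lists can be background, as these lists were not thresholded.

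**Figure D5:**
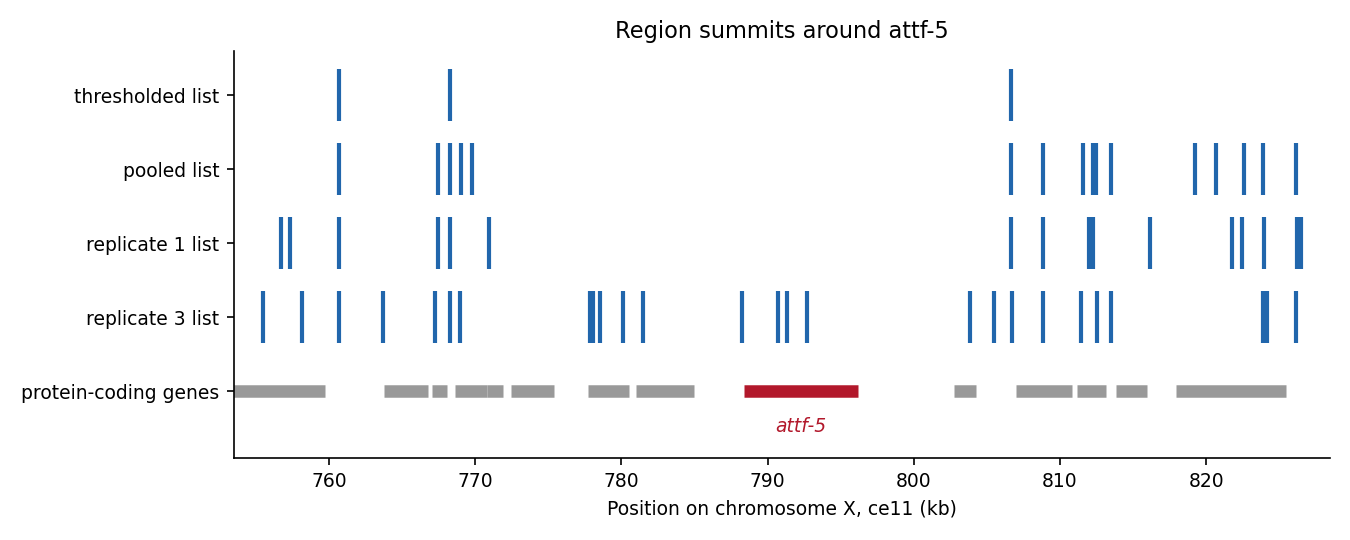
Region summits of the 4 peak lists (blue ticks) and protein-coding genes (grey bars, attf-5 in red) on chromosome X in ce11, position in kb. The replicate 3 list has 11 regions between the replicate 1 summits at 770923 and 806680, where the replicate 1, pooled and thresholded lists have none.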

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

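Shuffled sequences as the 6-mer control and the counting of piRNA genes apart from other noncoding RNA genes were the tests here chosen only after the result was seen. Of the 11 enriched lists, all were enriched under each of the other alternatives, the rotation test included, and 8 against a background of genes with any pooled region. The rotation test compares a list with random positions and not with other genes, so passing it adds little to these 11 calls. The strongest regions of the pooled list gave the same count as the peaks in each annotation class, so that setting was no separate check. Of the 8 depleted lists, 7 or 8 were kept under every alternative but the rotation test, which kept 1; the list lost where 7 were kept was that of major sperm proteins. Of 77 named protein-coding genes, 59 were still bound when each peak went to the nearest 5′ end within 2000 bp, 68 with the smaller promoter window, and 75 to 77 otherwise. The promoter share, centres against arms and the lower AT content at summits kept their direction and side of the threshold under the alternatives run for them, and the noncoding types that passed numbered 5 to 7. Of the annotation classes, 3′ UTRs no longer passed without replicate 3 and lay above rotation there (2.82% against 2.58%, adjusted permutation p = 0.424), 5′ UTRs passed with the smaller window (adjusted permutation p = 4.67e-04), and chromosome III passed when the chromosomes were adjusted without the arms (0.0456).

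The share of peaks with a summit in both replicates was 98.9% for peaks with signal above the median and 88.8 to 90.3% for the top regions of a single replicate. It was 99.5% when any shared base counted, 84.2% with 50% reciprocal overlap and 76.5% with summits within 50 bp. The shares under these overlap rules follow from what counts as shared, as the peaks stay the same. Those for peaks above the median signal and for a single replicate come from other sets of peaks. The top regions of a single replicate have a summit in that replicate by construction.

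With the peaks of signal above the median, 1484 genes were bound and 13 gene classes were enriched, as fewer peaks were used. The rotation test gave 17 enriched and 1 depleted list and 42 enriched gene classes. The background of genes with any pooled region gave 8 enriched classes, from fewer genes. The shuffled control gave 266 6-mers, and the cause was not tested. Of the transgene loci, 1 gained a peak without replicate 1 and 0 without replicate 3: attf-5, in the strongest regions of replicate 3.

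Under the rotation test, 10 lists went from below to above 1. Their counts over the rotated mean, with 0.5 added to both, were 2.88 for nuclear hormone receptors, 2.13 for xenobiotic metabolism, 2.66 for germline and oocyte markers, 1.17 for F-box and MATH domain genes, 1.04 for cuticle collagens, 1.71 for histones, 1.56 for homeobox genes, 1.45 for cilium genes, 1.34 for intestine and 1.04 for pharynx. Of these, the first 3 passed under that test. By construction it compares a list with random positions and not with other genes, which as a whole were bound more often than random positions.

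Lists that passed in neither setting also crossed an odds ratio of 1. Fatty acid metabolism gave 0.605 with peaks above the median signal, 0.734 to 1.43 without a replicate and 0.709 with the pooled background. Nuclear hormone receptors gave 0.831 to 1.05 without a replicate and 1.21 with the nearest 5′ end, where germline and oocyte markers gave 1.56 and coelomocyte and excretory cell markers 0.196. The last gave 0.762 with the smaller window and 0.820 with the pooled background, where other transcription factor families gave 0.953 and small RNA pathway genes 0.743. Without a replicate, vitellogenins gave 0.544 to 2.05 and neuron markers 0.955 to 1.20. The cause was not tested. Read depth was not given, so its effect was not tested.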

Other observations

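Of the tests below, those of summits in coding exons and of promoters next to tRNA genes were chosen only after the result was seen, as were the comparisons of tRNA genes and of peaks away from promoters. No biological explanation was tested, since the samples form 1 group.

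The enrichment of ribosomal, translation, splicing and other housekeeping lists was weighed against 2 technical explanations. Base composition of promoters, taken over 400 bp upstream, would leave little enrichment among promoters of like AT content. Yet 11 of 11 lists kept an odds ratio with its 95% interval above 1 within 10 strata of that content. For ribosomal proteins it was 31.9 (interval 18.2 to 56.2). Their mean AT content was 66.2% over these 400 bp, against 66.0% for all protein-coding genes, so the strata could change little for them. Base composition closer to the summit was not tested. Signal spread over transcribed gene bodies would raise summits in the coding exons of these genes, and there the peaks are too few to decide: 2 summits lay in 692.7 kb of such exons outside promoter windows and 56 in 18926 kb of other genes, a density ratio of 0.976 (exact 95% interval 0.115 to 3.69). This ratio cannot tell whether such summits were raised over other genes. Yet only these 2 summits lay in the exons, while 306 of the 645 genes had a promoter peak. Coding exons of all genes held 1.74% of summits against 19.6% (SD 0.783) under rotation. These values argue against spread signal as the source of most of these promoter peaks, though coverage below the peak lists was not analysed. Recovery of these promoters with many tagged proteins alike stays open, since no map of another factor or of an untagged strain was analysed here.

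The stretch around attf-5 without a region in the replicate 1 and pooled lists could be a chance gap. Gaps as long numbered 175 in the replicate 1 list and held 1529 genes, 7.66% of protein-coding genes, so chance is not excluded. Replicate 3 had 1.14 times as many regions per kb inside the gap as in the 50 kb on either side. As many replicate 3 regions per kb were found in 3 of the 175 gaps (1.71%), so such a density was rare among them. However, the 175 include the attf-5 gap itself, which no other is shorter than, and 15 hold no replicate 3 region. As the gaps are not alike, a chance difference between the lists is not excluded. Control coverage raised by the transgene copies and a difference between the replicates in coverage of the transgene stay open, as alignments were not analysed here.

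Peaks at tRNA genes could belong to neighbouring promoters. Of the 294 tRNA genes with a peak, 80.6% (95% interval 75.7 to 84.7%) lay outside every promoter window, which argues against this for most of them. The share with a peak was 47.4% of 500 outside and 50.9% of 112 inside promoter windows. It was 47.1% of 276 on X and 48.8% of 336 on the autosomes (odds ratio 0.934, Fisher's exact test, two-sided, p = 0.685). Whether tRNA genes are recovered with other tagged proteins stays open.

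Among tRNA products with at least 10 genes, the share with a peak ran from 3 of 19 for tRNA-Tyr to 10 of 13 for tRNA-Cys. It was 32 of 46 for tRNA-Lys and 23 of 34 for tRNA-Ala. The median offset of the summit from the tRNA 5′ end was 12.5 bp, with quartiles of −18 and 50 bp.

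The 1165 peaks outside promoters, tRNA and snoRNA genes differed in sequence from promoter peaks. GAGAGA lay near 51% of them and near 36.1% of promoter peaks (odds ratio 1.84, adjusted p = 4.56e-15, Fisher's exact test, two-sided). GAGCGC lay near 12.7% and 20.3% (odds ratio 0.573, adjusted p = 1.78e-07, Fisher's exact test). ACGCAG differed less, near 28.1% and 24.2% (odds ratio 1.22, adjusted p = 0.0204, Fisher's exact test). No control positions away from promoters were compared, so a difference between the surrounding sequences was not tested.

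The strongest peak outside every promoter window was at chromosome I 2639584 to 2640074, with a signal of 1328, 1167 bp downstream of the 5′ end of F40E3.3. The longest gap in the replicate 1 list, at V 2343789 to 2566183, spans 222394 bp and 48 protein-coding genes and holds no region of any list. The largest log2 ratio of replicate 1 to replicate 3 among promoter peaks was 2.85 at fbxb-72 and the lowest was −1.97 at ZK112.4. These genes and regions were chosen after their values were seen. The share of genes bound was 17.2% in the lowest of the 10 strata of promoter AT content and 6.51% in the highest.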
